A study of Caenorhabditis elegans with 2 samples.

How the data were processed

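Total RNA of wild-type N2 worms was isolated with Trizol and biotin-labelled cRNA was hybridised to an Affymetrix C. elegans array, per the labels' protocols. The labels give 1 array for worms exposed to anatase nanoparticles at 500 µg/ml and 1 array for unexposed worms; both are called replicate 3, and other replicates were not analysed here. The age of the worms and the length of the exposure are not given in the sources used here. The values deposited by the authors are intensities on a linear scale, 1 per probe set and array. The submitters' processing notes name Transcriptome Analysis Console; its version, the summary algorithm and the scaling method are not given in the sources used here. The trimmed means of both arrays lie close together, so the arrays look scaled to 1 level. The table held 22548 probe sets, no control probe sets and no detection calls, so whether a dim probe set lay above background is unknown.

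The platform annotation names exactly 1 gene for 20766 probe sets and several genes for 887, and 895 are unnamed here. Only the probe sets with 1 gene were used. Their gene numbers were matched to a RefSeq gene table of assembly WBcel235 for 99.7% of them, with 0 differing symbols; as the array names no build, no coordinates are printed. Old symbols in the lists were matched only where the annotation carries them.

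Intensities were converted to log2(intensity + 16), which understates the folds of dim genes, and the log2 values of a gene's probe sets were averaged. This gave 17118 genes. A gene was kept if its value on its brighter array reached the 25th percentile of all probe sets on that array, which left 13606. Without this filter 271 genes were at least 2-fold higher and 596 at least 2-fold lower. All differences are exposed minus control. Counts took differences of at least 2-fold. No test, p-value or standard error was computed between the arrays. The technical spread was taken from genes with exactly 2 probe sets, as the SD of the difference between both, divided by the square root of 2.

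Gene lists were fixed before the data were examined. They are metal response, iron and haem handling, cytochrome P450, UDP-glucuronosyltransferase, glutathione S-transferase, ABC transporter, oxidative stress, cytosolic heat shock, endoplasmic reticulum and mitochondrial unfolded protein response, C-type lectin, lysozyme, antimicrobial peptide, infection response, vitellogenin, cuticle collagen, moulting and hedgehog-related, sperm, germline, eggshell, fatty acid desaturase and elongase, fatty acid oxidation, lipid binding and lipase, muscle, neuron, neuropeptide, intestine, gut and lysosome peptidase, autophagy, ribosomal protein, proteasome, respiratory chain, DNA damage, histone, nuclear hormone receptor, chemoreceptor, and F-box and MATH domain genes. The median difference of a list with at least 5 measured genes was set against 10000 random lists of the same size, drawn from the same 20 bins of mean log2 value, and a list stood apart outside percentiles 2.5 to 97.5.

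Named genes were the 15 largest differences in each direction among genes whose brighter array reached the median of all probe sets and whose probe sets all differed in 1 direction, the 4 largest differences of each list, and 13 genes fixed in advance, of which 12 were measured (act-1 had no probe set naming it alone). The text gives a selection of the list members. mtl-2, elo-5 and elo-6 are each in more than 1 list.

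The steps were tested on simulated data over 13606 genes, with normal noise centred on 0. Its width came from the median absolute deviation of these arrays in each of the 20 bins. Heavier tails and the lower reading of dim genes were not simulated. Of 200 genes changed 4-fold, 98% were recovered past 2-fold, and 454 of the 13406 other genes also passed 2-fold. Those others include the 20 genes of the shifted list described next. A list of 20 genes shifted by 0.5 log2 units lay at percentile 100 and an unshifted one at 47.6, and 6% of 200 unshifted lists stood apart. Because the simulated spread came from the arrays themselves, it holds any real differences too.

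Alternatives fixed in advance were centring on the median, a loess correction with a span of 30%, quantile normalization, no brightness filter or 1 at the median, the brightest probe set of a gene in place of the mean, leaving out probe sets of the types that can pick up related transcripts, pseudocounts of 1 and 64, thresholds of 1.5-fold and 3-fold, and random lists not matched in brightness. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.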

Results

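Gene expression was measured in whole wild-type nematodes of the N2 strain, 1 array from worms exposed in the dark to anatase at 500 µg/ml and 1 array from worms without it. Anatase is a crystal form of titanium dioxide, given here as nanoparticles suspended in a liquid worm medium. The comparison asks which transcripts differ when worms meet these particles without light. Each array gave an intensity for 22548 probe sets. The median intensity was 123.1 on the control array and 117.8 on the exposed array, and 15.82% and 17.98% of probe sets lay below an intensity of 16. The 2%-trimmed means were 495.1 and 494.6. With 1 array per group there is no replicate error, so no difference below has a replicate check or a test, and the number of arrays limits the precision.

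Exposed worms had much lower signal for the metallothionein mtl-2, for the collagen gene lon-3 and for the histone H1-like gene hil-6, and higher signal for the C-type lectin clec-70 and for cysl-2, a gene of the cysteine synthase family. All but mtl-2 were read by 1 probe set, and the exposed value of lon-3 lay at the floor of the array. mtl-2 and cysl-2 were read only by probe sets of types that can pick up related transcripts. Among gene groups, cytosolic heat shock genes and sperm genes lay higher in the exposed array. Vitellogenins, antimicrobial peptides, cuticle collagens and nuclear hormone receptors lay lower. Most genes differed little: 81.2% of the 13606 genes bright enough to be compared lay within 0.5 log2 units of equal signal. Across probe sets, which are not independent replicates, the log2 intensities of both arrays had a Pearson r of 0.981 and a Spearman rho of 0.970.

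At least 2-fold differences were found for 226 genes higher and 418 genes lower in the exposed array, so 35.1% of them were higher. The counts depended strongly on the treatment of dim genes: they were 423 and 803 with a pseudocount of 1, 12 and 24 with a pseudocount of 64, and 25 and 54 among genes whose brighter array reached the median. The split depended on how the arrays were scaled. It was 253 higher and 361 lower with each array centred on its median (41.2% higher), 289 and 304 after a loess correction (48.7%), and 291 and 309 after quantile normalization (48.5%). Of the genes past 2-fold, 561 lay in the dimmest of 4 equal brightness groups, where the SD of the gene differences was 0.68 log2 units, against 0.23 in the brightest group. In that brightest group 3 genes were at least 2-fold higher and 8 at least 2-fold lower. Dim genes as a whole read lower on the exposed array: the median difference was −0.19 in the dimmest group and 0.01 in the brightest. Of all genes compared, 53.2% were lower. Medians and counts of dim gene families below hold this shift too, as do the random lists matched in brightness. The only technical spread within these data comes from genes measured by 2 probe sets: across 2293 such genes the SD of 1 probe set was 0.32 log2 units, and 58.1% of the pairs had the same sign. The differences read by both probe sets had a Pearson r of 0.20 across these genes. For most genes, 1 probe set thus told little of the difference read by another.

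**Figure D1:**
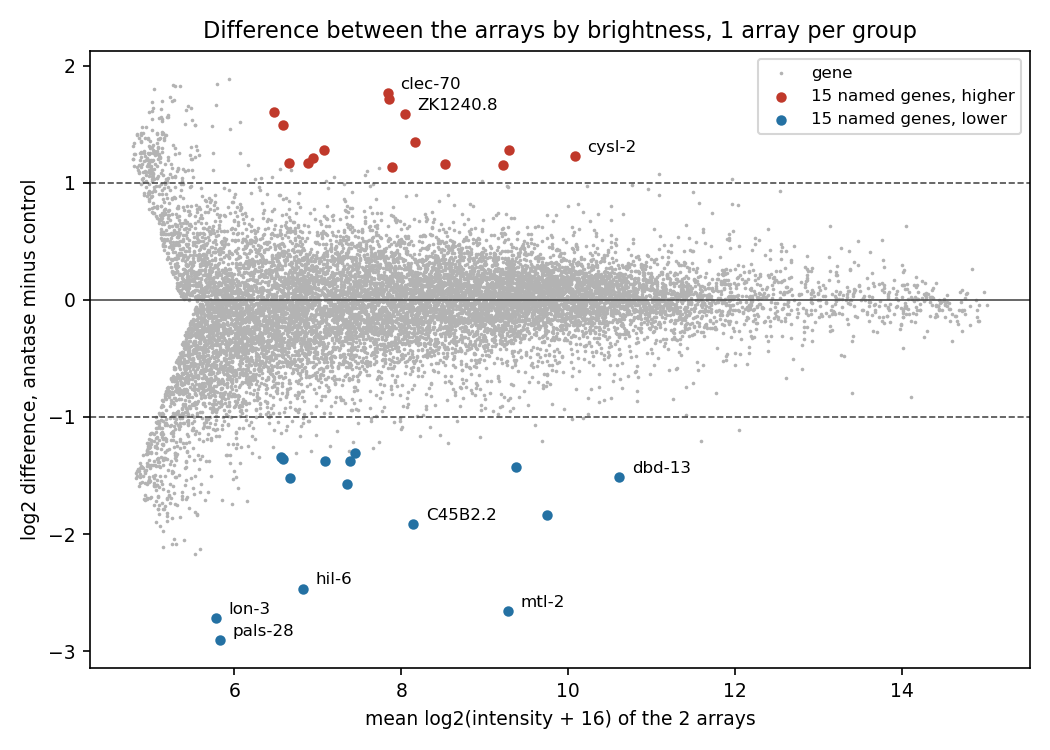
Log2 difference (exposed anatase array minus control array) of each of 13606 genes against its mean log2(intensity + 16), with 15 named genes higher in red and 15 lower in blue and dashed lines at 2-fold. The spread narrows with brightness, from an SD of 0.68 in the dimmest group to 0.23 in the brightest, and the empty wedge at the left comes from the filter on the brighter array.

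Among brighter genes whose probe sets all differed in 1 direction, the largest lower value belonged to pals-28, with a log2 difference of −2.90. Its intensity was 140 on the control array and 4.80 on the exposed one. The collagen gene lon-3 had a log2 difference of −2.71, from 125 to 5.50. mtl-2, a metallothionein that binds metal ions, stood at an intensity of 1540 on the control array and 231 on the exposed array, a log2 difference of −2.65. Its 3 probe sets gave −2.68, −3.11 and −2.17, and all 3 belong to the types that can pick up related transcripts, here called shared probe sets. dod-24 and ZK180.6, also lower, were read by shared probe sets alone as well. The related metallothionein mtl-1 was at −0.92. hil-6 was at −2.47, C45B2.2 at −1.91 and srlf-34 at −1.84. dbd-13, among the brightest of these genes, went from 2629 to 912, a difference of −1.51. The lectin gene clec-101 was at −1.57 and dod-24 at −1.38, and lower values were also found for T12B3.2 (−1.52), C49G7.12 (−1.43), ZK180.6 (−1.38), srlf-35 (−1.36), B0198.2 (−1.34) and R11E3.2 (−1.31). Apart from mtl-2, each of these 15 lower genes was measured by 1 probe set, so no agreement between probe sets was checked for them. The near-zero exposed values of pals-28 and lon-3 lie at the floor of the array, so their folds and their ranks are not well fixed.

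In the other direction the largest value was that of clec-70, at 108 on the control array and 405 on the exposed one, a log2 difference of 1.76. The chemoreceptor-family gene srr-6 was higher by 1.71 and srx-11, of the same kind, by 2.82-fold; K08C9.7 was higher by 1.60 and ZK1240.8 by 1.59. cysl-2 was among the brightest of the group, at 689 and 1638, higher by 1.23. The carboxylesterase-family gene cest-1.1 and T28F4.4 were each higher by 1.28, the ligand-gated channel gene lgc-1 by 1.21 and kreg-1 by 1.16. Y75B8A.28 (1.35), ctg-2 (1.17), C34E7.3 (1.17), T02E1.7 (1.16) and F47B8.3 (1.14) made up the rest of the 15. Each of these 15 genes was measured by 1 probe set, and for cysl-2, K08C9.7 and ctg-2 it was a shared one.

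Of 17 measured cytosolic heat shock genes, chaperones that help proteins fold, 14 were higher and 3 lower in the exposed array, with a median log2 difference of 0.28. That median lay above all 10000 random lists matched in brightness, and it was 0.50 with the brightest probe set and 0.51 without shared probe sets. The small heat shock gene hsp-12.3 had the largest value, 0.98, followed by hsp-16.41 and hsp-70 at 0.63 each and hsp-12.6 at 0.61. hsp-16.2 was at 0.50. On the control array hsp-70, hsp-16.2 and hsp-16.41 already had intensities of 13575, 9527 and 7206, against an upper quartile of 560. Genes of the hsp-16 family are near-identical copies, so these values may be shared between them. The oxidative stress list (31 genes) had a median of 0.06, with gpx-3 at 0.59, gpx-7 at 0.58 and the thioredoxin gene trx-3 at −0.98; sod-3 was at 0.16. The endoplasmic reticulum list (19 genes) had a median of 0.02, which turned to −0.0069 under quantile normalization and to −0.05 with the brightest probe set, and hsp-4 was at 0.52. The mitochondrial unfolded protein list (9 genes) had a median of 0.05, which was −0.0029 without shared probe sets, and hsp-6 was at 0.34. These 3 medians lay inside the middle 95% of random lists, but with the brightest probe set the oxidative stress median was 0.12, at percentile 99.2, above that range. The DNA damage list (23 genes) had a median of 0.05 and a mean of −0.05, lay inside the range, and had a median of −0.13 without shared probe sets.

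The metal and detoxification lists were mixed. The metal response list (11 genes, 5 lower) had a median of 0.01 but a mean of −0.38; without the brightness filter the median was −0.07. Its lowest members were mtl-2, mtl-1 and, at low brightness, the cadmium-response gene cdr-1 (−0.82). Iron and haem genes (9) had a median of 0.02, which was 0.24 without shared probe sets (percentile 96.8), and a mean of −0.11, with the metal transporter gene smf-2 at −1.74 at low brightness. Of 55 UDP-glucuronosyltransferases, which attach sugars to toxic compounds, 37 were lower, with a median of −0.16; ugt-2 was at −1.26, ugt-22 at −1.21 and ugt-26 at −1.17. This list lay just outside the random range, at percentile 2.46, and returned inside it in 8 of 10 alternatives. Cytochrome P450 genes (54) had a median of −0.04 and glutathione S-transferases (39) a median of −0.05, both of which turned positive under each of 3 scalings, and the P450 median also with the brightness filter at the median (0.05). The mean of the transferases was 0.05, and gst-4 was at −0.24 and cyp-35A2 at −0.43. ABC transporters (40) had a median of −0.16, inside the random range, with abt-4 at −0.95 and pgp-5 at −0.86. That median was 0.05 with the brightness filter at the median, and at −0.16 it lay below random lists not matched in brightness, at percentile 1.41.

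Immune genes were lower in part. Of 54 antimicrobial peptide genes, 42 were lower, with a median of −0.39, below all 10000 random lists. The 4 largest differences were at low brightness: thn-3 −1.46, cnc-1 −1.44, thn-4 −1.32 and cnc-5 1.25. Among brighter members, chosen after their values were seen, cnc-7 was at −1.16 and spp-14 at −1.12. The infection response list (18 genes, 10 lower) had a median of −0.17, at percentile 2.08, with irg-2 at −0.84, irg-1 at −0.56 and fmo-2 at 0.71; it returned inside the random range in 5 of 10 alternatives, and its median was −0.31 with the brightest probe set. C-type lectins (137, median −0.08) and lysozymes (13, median −0.05) lay inside the range. The lectin median was 0.04 with the brightness filter at the median, and the lysozyme median turned positive with each array centred on its median, and ilys-2 was at −0.90 and ilys-3 at −0.63.

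The cuticle and reproduction lists differed in direction. Of 134 cuticle collagens, 111 were lower, with a median of −0.27, below all random lists. Apart from lon-3, the members with the largest differences were dim and higher (col-127 1.31, col-45 1.30, col-52 1.07). Moulting and hedgehog-related genes (96, 71 lower) had a median of −0.24, with grl-13 at −1.62 and nas-27 at 1.16, both at low brightness with 1 array near the floor, so their folds are not well fixed. This median came inside the random range, at −0.19, without shared probe sets. Of 68 sperm genes, many of them near-identical major sperm proteins, 58 were higher, with a median of 0.16, above all random lists; spe-49 was at 1.45 at low brightness, spe-36 at 0.56 and spe-11 at 0.54. The 5 vitellogenins, yolk proteins made in the intestine, had a median of −0.47: vit-5 was at −0.79, vit-1 at −0.49, vit-4 at −0.47 and vit-6 at −0.26, and vit-2 (named after its value was seen) at 0.02. vit-4 and vit-5 were read only by shared probe sets. Germline genes (37) had a median of 0.04 and eggshell genes (13) a median of −0.06, both inside the random range. The eggshell median was 0.00 when each array was centred on its median and 0.08 without shared probe sets, and with the brightest probe set it was −0.15, at percentile 0.475, below the range.

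**Figure D2:**
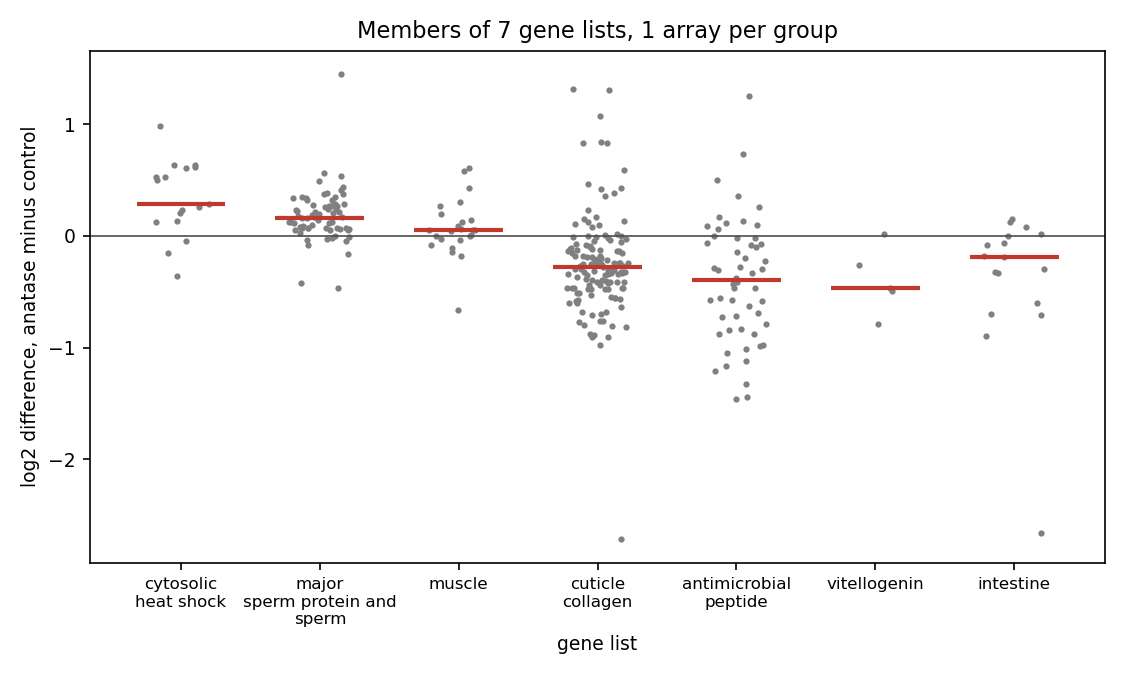
Log2 difference (exposed anatase array minus control array) of each member of 7 gene lists, 1 point per gene, with a red line at the list median. Medians are 0.28 for heat shock, 0.16 for sperm and 0.05 for muscle, against −0.27 for cuticle collagen, −0.39 for antimicrobial peptides, −0.47 for vitellogenins and −0.19 for intestine.

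Tissue and metabolic lists completed the comparison. The intestine list (17 genes, 12 lower) had a median of −0.19, with the peptide transporter gene pept-1 at −0.90, the phosphatase gene pho-1 at −0.71 and ifd-2 at −0.70; it also holds mtl-2. Gut and lysosome peptidases (25, 18 lower) had a median of −0.12, with asp-9 at −0.95 and cpr-5 at −0.75, and lipid binding and lipase genes (27, 18 lower) a median of −0.15, with far-3 at −1.07 and far-6 at −0.76. Against random lists not matched in brightness, these 3 lists no longer stood apart, and the peptidases did not without shared probe sets either (percentile 4.03). The intestine median was −0.29 without shared probe sets. Muscle genes (24) had a median of 0.05, which was 0.0099 with the brightest probe set and 0.012 without shared probe sets, and neuronal genes (25) a median of 0.01, with a mean of −0.09 and a median of −0.18 with the brightest probe set and −0.05 without shared probe sets. Fatty acid desaturase and elongase genes (21, median −0.07, fat-7 −0.61), fatty acid oxidation genes (45, median −0.06, −0.0013 without shared probe sets, acs-1 −0.78), autophagy genes (26, median −0.08) and neuropeptide genes (64, median −0.09) lay inside the random range, the neuropeptides only until shared probe sets were left out (−0.15, percentile 1.90).

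Of 181 nuclear hormone receptors, a large family of transcription factors, 128 were lower, with a median of −0.15, at percentile 0.415; the largest single difference, nhr-247 at 1.89, went the other way at low brightness. Chemoreceptors (376 measured) had a median of −0.36, below all random lists (−0.19 after the loess correction), but only 9 of them were above the median brightness. With that stricter brightness filter the median was −0.21 and inside the random range. Ribosomal protein genes (75, 56 lower) had a median of −0.05 at percentile 0.945, and came inside the random range in 5 of 10 alternatives. With each array centred on its median, which moves all genes alike, the median was 0.0015 and the list stayed below the range, at percentile 0.995. The proteasome (33, median −0.04, turning positive under the same centring), respiratory chain (42, median 0.05), histone (25, median 0.03, mean −0.0013, median −0.06 without shared probe sets) and F-box and MATH domain (257, median −0.01) lists lay inside the range. The F-box median turned positive under each of 3 scalings and with the brightness filter at the median (0.03), and with no filter it was −0.025, at percentile 98.4, above the range. Of the reference genes, pmp-3 was at −0.36, and tba-1 at −0.04 and cdc-42 at −0.03 both turned positive with each array centred on its median. Shared probe sets alone also read hsp-70, hsp-4, pgp-5, cnc-1, cnc-7, col-127, pho-1, ifd-2, cpr-5, far-3, tba-1 and cdc-42.

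Over the 37 lists fixed before the data were examined, 2 stood above and 12 below the middle 95% of random lists, against 1.85 that chance would give for lists of unrelated genes. Of the 23 lists inside the range, 14 had a median whose sign turned in at least 1 alternative, and 5 left the range in at least 1. Some signs, as for lysozymes and the proteasome, turned only with centring on the median, which moves all genes alike. Members of a gene family can be read by shared probes or vary together, so more lists than that can stand apart without any effect of the exposure. The percentile of a list describes these 2 arrays only.

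**Figure D3:**
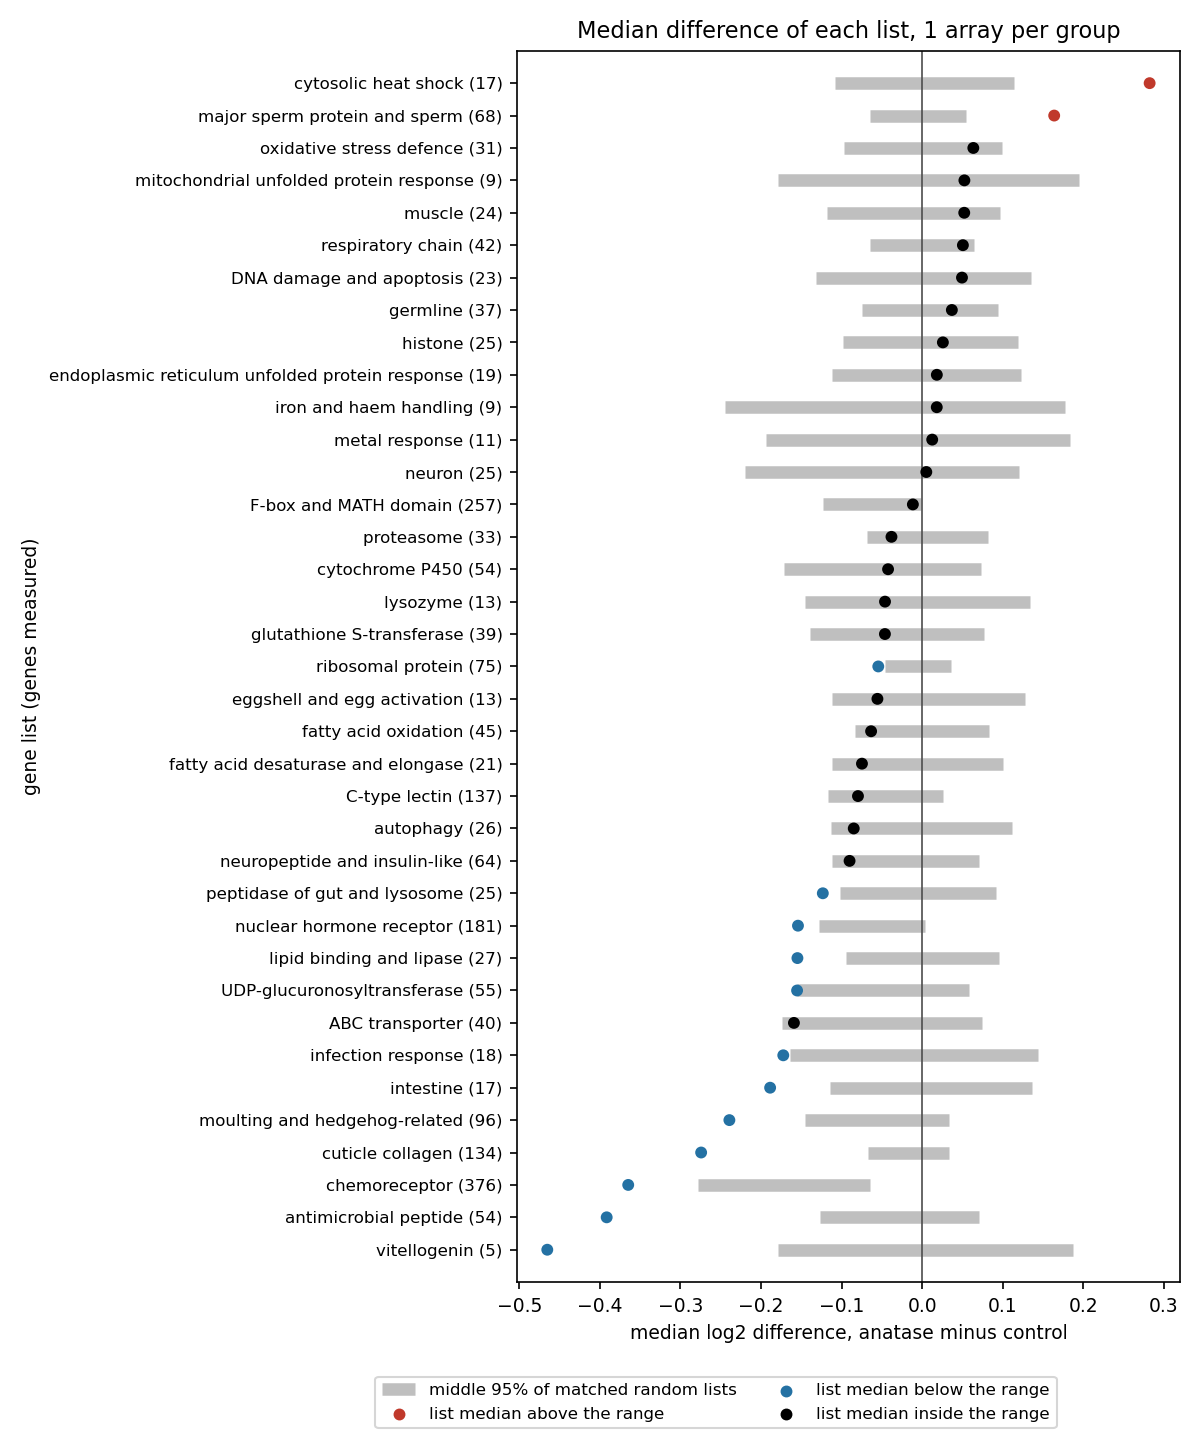
Median log2 difference (exposed anatase array minus control array) of each of 37 gene lists, with the number of genes measured in brackets and grey bars for the middle 95% of 10000 random lists matched in brightness. Red points lie above the bar, blue points below it and black points inside it; heat shock (0.28) and sperm (0.16) are the 2 lists above.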

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

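The list of hypoxia-inducible factor targets was added after the data were seen, as were its alternatives; all others were fixed before. No paired analysis was possible because each group has 1 array. Of the 14 lists standing apart, 6 stayed so in each alternative that gave a value (heat shock, sperm, antimicrobial peptide, vitellogenin, cuticle collagen, nuclear hormone receptor); vitellogenins had too few genes without shared probe sets. Of the 23 others, 18 stayed inside the random range throughout. Counts at least 2-fold higher and lower were 423 and 803 with a pseudocount of 1, 12 and 24 with 64, and 25 and 54 with the brightness filter at the median; they were 638 and 1303 at 1.5-fold and 23 and 76 at 3-fold. Medians that came inside the range were, for UDP-glucuronosyltransferases, −0.095 with median centring, −0.073 with loess, −0.069 with quantile normalization, −0.16 with the brightest probe set or without shared probe sets, −0.10 with a pseudocount of 64, −0.14 with no filter and −0.075 with the filter at the median. For infection response they were −0.11 with loess or a pseudocount of 64, −0.10 with quantile normalization and −0.17 without shared probe sets or against unmatched lists. Ribosomal proteins came to −0.039 (loess), −0.023 (quantile), −0.044 (brightest probe set) and −0.055 (without shared probe sets, or unmatched), while median centring, which moves all genes alike, gave 0.0015, a reversed sign with the list still below the range at percentile 0.995. Without shared probe sets moulting genes came inside at −0.19 and peptidases at −0.14. Against unmatched lists peptidases (−0.12), lipid binding genes (−0.15) and intestine (−0.19) did, and with the filter at the median chemoreceptors (−0.21). Lists that came to stand apart were ABC transporters against unmatched lists (−0.16), oxidative stress (0.12) and eggshell (−0.15) with the brightest probe set, neuropeptides without shared probe sets (−0.15) and F-box genes with no filter (−0.025). The unmatched lists changed the random range and not the medians; otherwise the cause was not tested. Of 854 recomputed values of named genes 7 moved by more than the probe set spread, among them mtl-2, at −3.11 with its brightest probe set, and 0 past 2-fold changed sign. Signal over background is unknown, which limits dim genes most.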

Other observations

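The loess correction, the brightest probe set and the omission of shared probe sets were fixed before the data were examined; the choice of these patterns, the chromosome medians, the muscle and eggshell tests and the list of hypoxia-inducible factor targets with its tests came after the values were seen. Each hypothesis was found and tested on the same 2 arrays.

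A look through the largest genes and gene-name families led from cysl-2, read only by a shared probe set, to other genes listed from memory as targets of the hypoxia-inducible factor, the transcription factor that responds to low oxygen. Of 15 such genes measured, leaving out cysl-2, 11 were higher and 4 lower in the exposed array, with a median log2 difference of 0.28, at percentile 99.99 of matched random lists. efk-1 was at 0.80, gst-19 at 0.73, rhy-1 at 0.72, nhr-57 at 0.69, sqrd-1 at 0.68 and ethe-1 at 0.46, and cysl-1 was at −0.32 and lgg-2 at −0.30. Of these, efk-1, gst-19 and ethe-1 were read by shared probe sets alone. The list was shortened once after these values had been seen, by leaving out cysl-1 and ftn-1 (0.02) and 2 names that were not measured; the shortened list of 13 genes had a median of 0.33. Membership rests on memory, was not checked, and is unsure for efk-1, cysl-1 and ftn-1 among others.

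Relative to genes of like brightness, genes on the X chromosome had a median log2 difference of −0.07 (1875 genes, 42.7% of them positive) and genes on chromosome V a median of −0.03. Medians on chromosomes I, III and IV lay between 0.02 and 0.03, and that on chromosome II was 0.01.

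Cuticle collagens, antimicrobial peptides and intestine genes lay lower and sperm genes higher. A brightness-dependent difference between the arrays is argued against. After the loess correction the collagen median stayed at −0.26 and that of antimicrobial peptides at −0.29, both below all random lists. Intestine genes stayed at −0.20 (percentile 0.12) and sperm genes at 0.16 (percentile 100). The random lists were already matched in brightness, so the loess results here and below are not a separate check. The muscle median was 0.052 (0.0099 with the brightest probe set, 0.012 without shared probe sets). It lay above the medians of collagens by 0.33, antimicrobial peptides by 0.44 and intestine genes by 0.24. The SD of the muscle genes, 0.26, describes single genes and not the error of a median, so it decides nothing here. The random range of the muscle list reached down to −0.118, above the medians of all 3 lower lists. These values argue against an equally lower share of RNA from all somatic tissues. A lower share from some tissues stays open, and the neuronal median moved from 0.0051 to −0.18 with the brightest probe set. Exposed worms at a slightly earlier stage may account for the pattern and stay open: the eggshell median, at percentile 16.7, lay neither low nor high. Only a median above the random range was set to count against this explanation. Worms of equal stage would lie in the middle as well, so this test could not exclude it. Vitellogenins (median −0.47, below the range) and germline genes (0.04, inside it) were not part of the test. Other choices of probe sets moved the eggshell median both ways, to −0.15 at percentile 0.475 with the brightest probe set and to 0.08 at percentile 86.9 without shared probe sets. An effect of the exposure itself stays open too, since with 1 array per group exposure, worm batch and stage cannot be told apart.

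Heat shock genes lay higher. Their median was 0.29 after the loess correction and 0.51 over the 12 genes left without shared probe sets, each above all random lists. The first argues against a brightness-dependent difference. The second shows that the shift did not rest on the shared types of probe set alone. It cannot exclude signal shared between near-identical copies, as hsp-16.2 and hsp-16.41 were read by other types and stayed in. The genes hsp-70, hsp-16.2 and hsp-16.41 were bright on the control array too, so high signal for them was not limited to exposed worms. Handling of the worms before RNA isolation and the exposure itself remain open and were not tested.

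The targets of the hypoxia-inducible factor lay higher. Their median stayed at 0.31 after the loess correction and was 0.22 without shared probe sets, at percentile 99.1, the first of which argues against a brightness-dependent difference. Higher activity of the factor in the exposed worms and lower oxygen in 1 of the liquid cultures both stay open and were not tested, since the only values here that bear on them are those of the pattern itself.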
